A study of Mus musculus with 6 samples.

How the data were processed

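RNA from 6 cultures of primary mouse Sertoli cells, 3 wild-type and 3 labelled Arhgef15 cKO, was sequenced. Per the labels, total RNA was extracted with TRIzol and the cells were grown in medium with serum and EGF. Groups were taken from the genotype label, and the titles number the biological replicates 1 to 3 in each genotype without naming a litter, day or batch. Where nothing says that cultures came from separate animals, p-values measure the spread between these libraries.

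The deposited files hold 1 value per gene and library. Per the submitters' processing notes, FastQC and HISAT2 2.1.0 were used with the genome build mm8. The counting tool, annotation and strand setting are not given in the sources used here. The unit was not stated and was taken from the values as FPKM, the deposited unit throughout: columns summed to between 291453.5 and 346688.4, and value times exonic length fell on whole multiples of 1 step per library. In single-exon genes with up to 10 fragments, 98.9% to 99.4% of the values were whole within 0.02 times their fragment number. The step was fitted to values of the same genes. Those steps gave 16790000 to 20320000 fragments per library. FPKM are not counts, so no count model was used. Gene identifiers included some newer than the reference annotation that gave the exonic lengths, which itself is later than mm8. The build named in the notes is therefore in doubt, and no coordinates are given. Of 29275 identifiers, 28932 matched a symbol and 343 did not. Without a stated strand, fragments of overlapping antisense genes cannot be separated. Gapdh, which has many pseudogene copies, was listed at only 3.35 to 9.38 FPKM while Actb was at 1461 to 4363 FPKM.

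Values were transformed to log2(FPKM + 1), so fold changes of low genes are understated. Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept, which left 12284. Genotype was the only term in limma 3.58.1 (R 4.3.3, eBayes with trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Arhgef15 lay below the filter and was fitted in the same model over all 29275 genes, with an exact permutation test beside it. Python 3.11.15 was used for tables and figures. The median log2 difference of all tested genes was 0.08, and it was 0.03 with median-ratio scaling and 0 with quantile normalization.

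A set of 25 gene lists was fixed before the data were examined, covering Sertoli function, other testis cell types and general responses. The 24 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with the estimated correlation and fry as alternatives. The estimated setting can raise p even where the correlation is not higher, as given below for the p53 list. The values of 1 of these lists and of 1 junction gene are not reported here. Named genes were Arhgef15, the 12 genes with the largest change in each direction past the threshold (non-overlapping groups, a group mean of at least 5 FPKM, no predicted genes or pseudogenes), or else the 5 with the smallest p, and up to 4 members of each list with the smallest p. The alternatives were other filters, pseudocounts of 0.1 and 5, median-ratio and quantile scaling, array weights, predicted genes left out, an adjusted p threshold of 0.1, the replicate number as a block, and each library left out in turn. A correction for GC content and length, and the estimated correlation within the other settings, were added after seeing the data. A second unit was not used, since each file holds 1.

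The fit was tested on simulated data with 12284 genes, of which 200 were changed, in 5 draws. With the spread of the 6 libraries it recovered 0.1% of genes changed 2-fold, 68.1% of genes changed 4-fold and 90.1% of genes changed 8-fold, with 0, 5.2 and 10.6 false calls per draw. With the spread taken without wild-type replicate 3, it recovered 29.2%, 84.4% and 95.2%, with 3.2, 7.8 and 9.6 false calls per draw. Both simulations had 3 libraries per genotype and noise drawn independently for each gene. False calls from structure shared between the real libraries are therefore not covered.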

Results

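Gene expression was measured by RNA sequencing in primary Sertoli cells, the somatic cells of the seminiferous tubule that nurse the germ cells, kept in culture after isolation from mouse testis. The 6 libraries comprised 3 numbered biological replicates from wild-type mice and 3 labelled as a conditional knockout (cKO) of Arhgef15 in Sertoli cells. Arhgef15 encodes a guanine nucleotide exchange factor. The comparison asked which transcripts differ in Sertoli cells when this gene is deleted. Each library was described by FPKM values of 29275 genes, of which 28932 were matched to a gene symbol. The step between neighbouring values put the depth at 18750000, 19500000 and 20320000 fragments in wild-type replicates 1, 2 and 3, and at 19380000, 16790000 and 20090000 in cKO replicates 1, 2 and 3. One fragment in a gene of 2000 bp corresponded to 0.0246 to 0.0298 FPKM.

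Arhgef15 (ENSMUSG00000052921) was not lower in the libraries labelled cKO. It was listed at 0.123, 0.0237 and 0.349 FPKM in wild-type replicates 1, 2 and 3, and at 0.501, 0.322 and 0.338 FPKM in cKO replicates 1, 2 and 3. The means were 0.165 ± 0.167 FPKM in wild-type and 0.387 ± 0.0994 FPKM in cKO libraries (SD, n = 3 each). These values rested on 15, 3 and 46 fragments in the wild-type libraries (exact Poisson 95% intervals 8.4 to 24.7, 0.6 to 8.8 and 33.7 to 61.4) and on 63, 35 and 44 fragments in the cKO libraries (48.4 to 80.6, 24.4 to 48.7 and 32.0 to 59.1). The intervals cover counting error only. The difference, 0.26 on the log2(FPKM + 1) scale with an SE of 0.13, did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.903 over 29275 genes), and an exact two-sided permutation test gave p = 0.3, where 0.1 is the smallest p that 3 against 3 allows. The deleted exons are not given in the sources used here, so a value over the whole gene may not report the deletion, and groups are therefore named throughout by their labels.

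A pair of ribosomal protein sequences fell in the libraries labelled cKO. Rps27rt (ENSMUSG00000050621), a retrogene copy of the ribosomal protein gene Rps27, had 487.8 ± 65.1 FPKM in wild-type and 50.3 ± 8.71 FPKM in cKO libraries (SD, n = 3 each), a log2 change of -3.26 with an SE of 0.22 (limma, adjusted p = 0.00899). Rps12-ps3 (ENSMUSG00000067038), a pseudogene copy of the ribosomal protein gene Rps12, had 1029 ± 89.2 FPKM in wild-type and 137.4 ± 26.2 FPKM in cKO libraries, a log2 change of -2.91 with an SE of 0.22 (limma, adjusted p = 0.0111). All 3 cKO values lay below all 3 wild-type values for both. Fragments of such copies can be shared with their parent genes and with other copies, so the level of each copy is uncertain. Summed over the parent gene and its named copies, fragments changed by -1.93 (log2) for Rps27 and by -1.16 for Rps12. All cKO sums lay below all wild-type sums in both families. Copies not named after the parent were not summed. Rps12-ps3 falls outside the rule for named genes and was named after its values were seen.

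**Figure D1:**
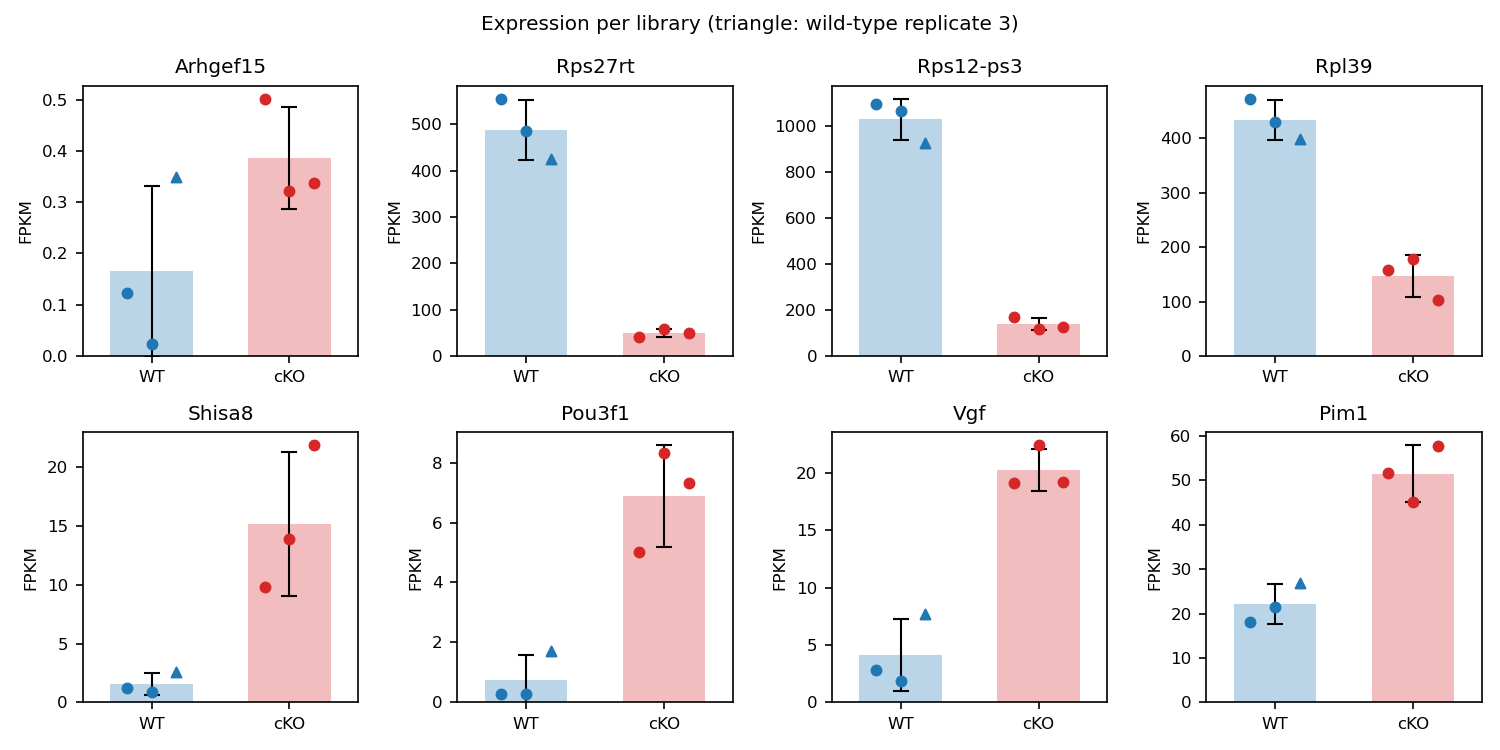
FPKM (linear axes) of 8 genes in the 3 wild-type and 3 cKO libraries, with points for libraries, bars for group means and error bars for the SD. Rps27rt and Rps12-ps3 are lower in all 3 cKO libraries, Arhgef15 is not, and wild-type replicate 3 (triangle) lies at 7.70 FPKM of Vgf, above the other wild-type libraries.

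These were the 2 genes past the threshold among 12284 tested, both lower and both by more than 2-fold, and 0 genes were called higher (limma, adjusted p under 0.05). At an unadjusted p under 0.05 there were 837 genes, 476 higher and 361 lower. Grouping wild-type replicates 1 and 2 with cKO replicate 1, 2 or 3 instead gave 1591, 1095 and 1459 such genes. The remaining groupings of 3 against 3 gave 15 to 695. The 3 cKO values lay above the 3 wild-type values in 772 genes and below them in 616, together 11.3% of the genes, where chance gives 10%. In coding genes other than those of ribosomal proteins this share was 10.3%, against 1.0% to 19.9% over the other groupings. Among genes that did not pass, Rpl39, a protein of the large ribosomal subunit, had 433.6 ± 37.1 FPKM in wild-type and 146.3 ± 38.8 FPKM in cKO libraries (adjusted p = 0.263). Rps27, the parent of Rps27rt, had 339.2 ± 71.1 and 119.3 ± 39.7 FPKM (adjusted p = 0.438), and Ctss, a lysosomal protease of phagocytes, had 97.2 ± 30.5 and 33.6 ± 6.90 FPKM (adjusted p = 0.438). Tmem256 had 31.6 ± 5.66 and 14.7 ± 0.600 FPKM (adjusted p = 0.401). On the other side, Shisa8 had 1.57 ± 0.931 FPKM in wild-type and 15.2 ± 6.14 FPKM in cKO libraries (adjusted p = 0.205). Pou3f1, a POU domain transcription factor, had 0.752 ± 0.832 and 6.87 ± 1.70 FPKM (adjusted p = 0.263), Tmem200b had 3.63 ± 1.41 and 14.1 ± 3.70 FPKM (adjusted p = 0.279), and the neuropeptide precursor Vgf had 4.14 ± 3.11 and 20.3 ± 1.86 FPKM (adjusted p = 0.346). Pim1, a serine/threonine kinase, had 22.1 ± 4.54 and 51.5 ± 6.37 FPKM (adjusted p = 0.357). The count of genes past the threshold depended on single libraries: it was 478 (304 higher, 174 lower) without wild-type replicate 3, 4 without wild-type replicate 1, and 0 without wild-type replicate 2 or without cKO replicate 1, 2 or 3. Where the count was 0 with a library left out, the log2 difference stayed at -3.13 to -3.38 for Rps27rt (adjusted p from 0.0530 to 0.127) and at -2.81 to -3.06 for Rps12-ps3 (adjusted p from 0.0530 to 0.166). The count was also 0 without the filter on low values.

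Wild-type replicate 3 stood apart from the other wild-type libraries. Across genes, its Pearson correlation was 0.860 with wild-type replicate 1 and 0.898 with wild-type replicate 2, against 0.947, 0.929 and 0.921 with cKO replicates 1, 2 and 3. Wild-type replicates 1 and 2 correlated at 0.962 with each other. On the first principal component, which carried 50.3% of the variance, wild-type replicates 1 and 2 scored 58.7 and 36.7, wild-type replicate 3 scored -40.1, and cKO replicates 1, 2 and 3 scored -19.6, -22.6 and -13.2. Genes are not independent replicates, so these correlations describe the libraries only.

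**Figure D2:**
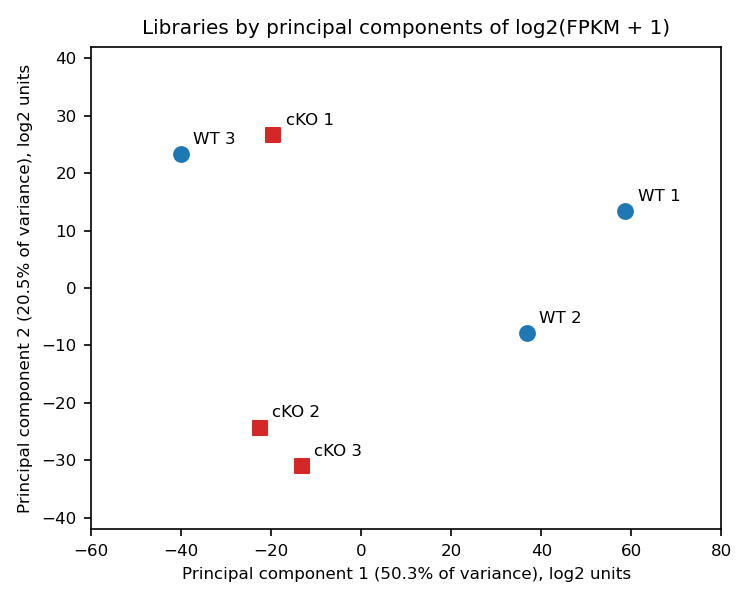
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), which carry 50.3% and 20.5% of the variance, with circles for wild-type and squares for cKO libraries. Wild-type replicate 3 lies on the side of the 3 cKO libraries, away from wild-type replicates 1 and 2.

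Sertoli cell markers had higher means in the libraries labelled cKO for 17 of 22 measured genes, with a median log2 difference of 0.72. Sox9, the transcription factor of Sertoli cell fate, had 10.4 ± 8.50 FPKM in wild-type and 27.3 ± 7.19 FPKM in cKO libraries (SD, n = 3 each). Wt1, another Sertoli cell transcription factor, had 7.30 ± 6.69 and 19.1 ± 5.25 FPKM. Gdnf, the Sertoli factor that maintains spermatogonial stem cells, was listed at 0.827, 0.879 and 11.4 FPKM in wild-type replicates 1, 2 and 3. In cKO replicates 1, 2 and 3 it was at 10.4, 8.48 and 11.2 FPKM, so wild-type replicate 3 was the highest library. The ligand Dhh had 0.555 ± 0.400 FPKM in wild-type and 1.80 ± 0.415 FPKM in cKO libraries. Genes of tight, adherens and gap junctions, which form the blood-testis barrier, were higher in 15 of 19 cases with a median of 0.67. Cgn, a tight junction plaque protein, had 2.71 ± 2.47 and 13.4 ± 8.45 FPKM, and Cdh2, the N-cadherin gene, 17.2 ± 5.02 and 30.2 ± 8.70 FPKM. As sets, both lists passed camera with a preset correlation (adjusted p = 0.00773 for Sertoli markers and 0.000404 for junction genes). Both calls were lost with an estimated correlation (adjusted p = 0.668 for each), and 0 members of either list passed over all genes or adjusted over the list alone. The mean log2(FPKM + 1) of Sertoli markers was 3.35 and 3.24 in wild-type replicates 1 and 2, 4.27 in wild-type replicate 3, and 4.25, 3.98 and 4.52 in the cKO libraries. That of junction genes was 2.90, 3.07 and 4.12 in wild-type and 4.03, 3.97 and 4.23 in cKO libraries. Without wild-type replicate 2, the Sertoli set no longer passed (adjusted p = 0.0540, preset correlation).

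Markers of other testis cells differed between libraries as well. Macrophage and leukocyte markers were lower in the libraries labelled cKO for 14 of 15 genes, with a median log2 difference of -1.32 (camera, preset correlation, adjusted p = 1.14e-10, but adjusted p = 0.668 with an estimated correlation). Lyz2, the lysozyme of myeloid cells, was listed at 647.8, 576.9 and 66.5 FPKM in wild-type replicates 1, 2 and 3 and at 69.2, 37.1 and 69.4 FPKM in the cKO libraries. Csf1r, the receptor for the macrophage growth factor CSF1, had 19.6 ± 7.88 and 7.46 ± 3.31 FPKM, and Fcgr3 had 27.8 ± 8.29 and 10.4 ± 6.10 FPKM. Endothelial markers were higher for 11 of 12 genes with a median of 0.87 (adjusted p = 0.000197, but adjusted p = 0.668 with an estimated correlation), among them Sox18 at 4.33 ± 2.34 and 12.1 ± 5.14 FPKM and Esam at 1.23 ± 1.33 and 3.73 ± 1.46 FPKM. Fibroblast and stromal markers were lower for 9 of 10 genes with a median of -0.34 (adjusted p = 0.00757, but adjusted p = 0.668 with an estimated correlation), led by Ogn at 20.2 ± 13.4 and 3.81 ± 2.57 FPKM. In wild-type replicate 3 the mean log2(FPKM + 1) of these 3 lists lay inside the cKO range. It was 5.05, 4.80 and 3.58 in wild-type and 3.77, 2.66 and 3.34 in cKO libraries for macrophage markers and 3.77, 4.17 and 3.09 against 3.08, 3.00 and 3.47 for fibroblast markers. For endothelial markers it was 2.54 in wild-type replicate 3 and 3.12, 2.17 and 2.49 in cKO libraries, with both other wild-type libraries below these. Spermatid markers, with 12 of 14 lower, and Leydig cell markers, with 6 of 8 lower, each passed at an adjusted p = 0.0389 (with an estimated correlation, adjusted p = 0.792 and 0.668). The mean log2(FPKM + 1) of spermatid markers was 3.21, 2.44 and 3.34 in wild-type replicates 1, 2 and 3 and 3.96, 2.18 and 1.30 in cKO replicates 1, 2 and 3, so that cKO replicate 1 was the highest library. That of Leydig markers was 4.66, 3.62 and 3.67 in wild-type and 3.87, 3.40 and 2.86 in cKO libraries. Among the Leydig genes, Hsd3b1, an enzyme of steroid synthesis, had 76.1 ± 65.3 and 14.0 ± 4.07 FPKM. Its value in wild-type replicate 3, 8.99 FPKM, lay below all cKO values, which were 11.6 to 18.7 FPKM. In these 5 lists, 0 members passed over all genes or adjusted over the list alone. At the preset correlation, the spermatid and Leydig calls ended, among other settings, with median-ratio scaling (adjusted p = 0.0610 for both) and without wild-type replicate 1 (0.220 and 0.429), wild-type replicate 3 (0.276 and 0.0644) or cKO replicate 3 (0.949, with the direction turned, and 0.322), and the spermatid call without cKO replicate 2 (0.108). The endothelial call ended with the stricter filter (0.191, 3 members left), and the fibroblast call with that filter (0.0918) and without wild-type replicate 2 (0.126).

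**Figure D3:**
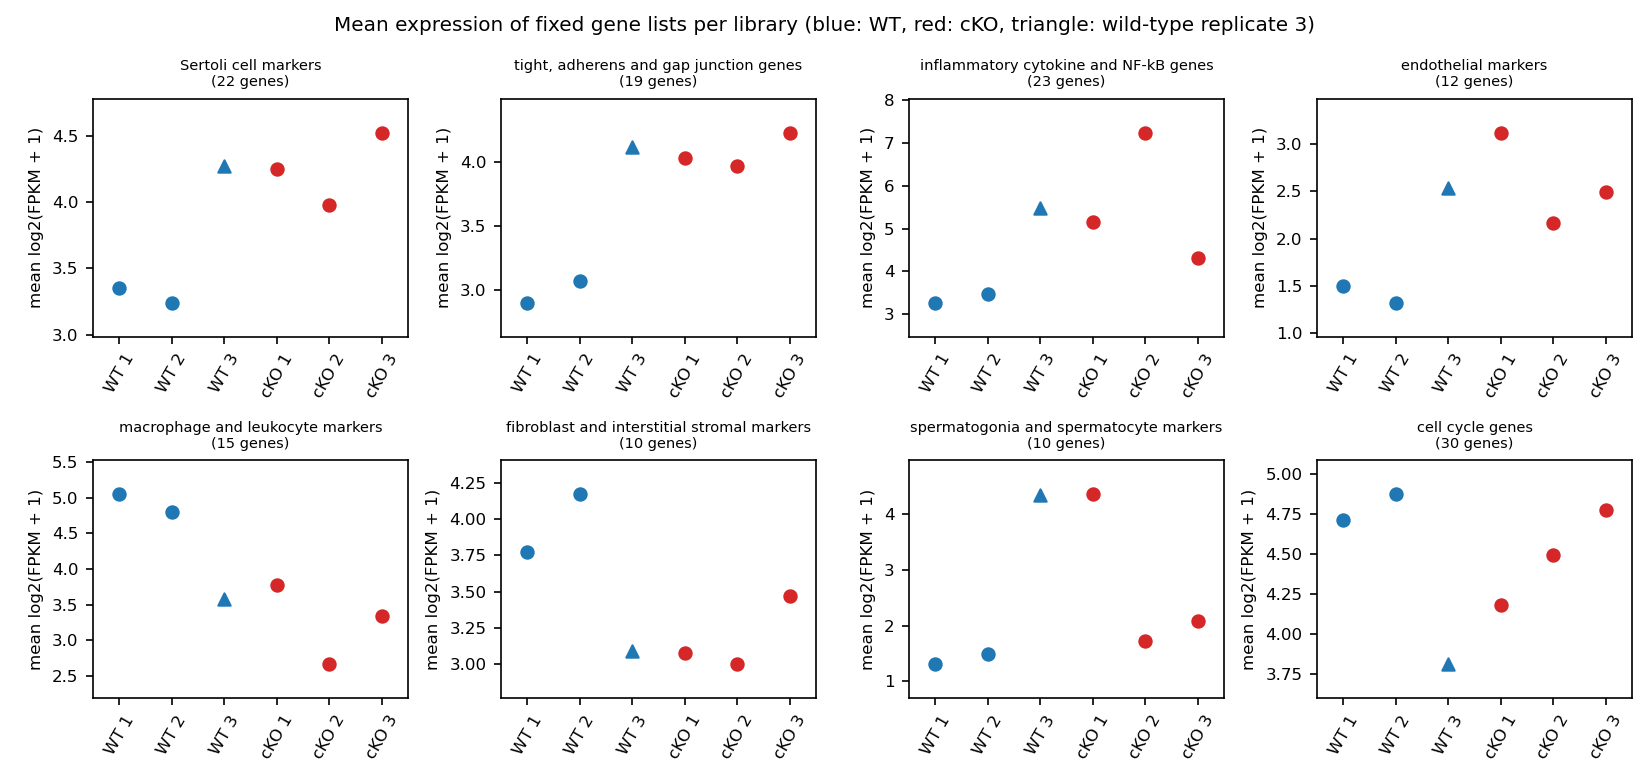
Mean log2(FPKM + 1) of 8 gene lists in each of the 6 libraries, 1 panel per list, with blue for wild-type and red for cKO libraries. Wild-type replicate 3 (triangle) lies inside the range of the cKO libraries for Sertoli, junction, inflammatory, endothelial, macrophage and fibroblast lists, and shares with cKO replicate 1 the high mean of spermatogonia and spermatocyte markers, 4.35 and 4.36.

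Inflammatory cytokine and NF-kB genes were higher in the libraries labelled cKO for 21 of 23 members, with a median log2 difference of 1.59 (camera, preset correlation, adjusted p = 0.000107, but adjusted p = 0.668 with an estimated correlation). The chemokine gene Cxcl5 was listed at 38.4, 139.3 and 379.4 FPKM in wild-type replicates 1, 2 and 3 and at 383.2, 1710 and 335.9 FPKM in the cKO libraries. Ccl5 had 5.30 ± 4.24 and 40.0 ± 46.0 FPKM, and Saa3, an acute phase gene, 47.9 ± 74.4 and 109.7 ± 80.7 FPKM. The spread between cKO libraries was as wide as the difference for both genes. Saa3 in wild-type replicate 3, at 133.7 FPKM, also lay above cKO replicates 1 and 3, at 68.1 and 58.2 FPKM. The list mean was 3.27, 3.47 and 5.47 in the wild-type libraries and 5.16, 7.23 and 4.32 in the cKO libraries. Interferon response genes were higher for 21 of 23 members with a median of 0.23 (adjusted p = 0.0413, but adjusted p = 0.792 with an estimated correlation), led by Rsad2 at 4.60 ± 3.96 and 15.7 ± 10.0 FPKM. The list mean was 3.99, 3.99 and 4.08 in the wild-type libraries and 3.64, 4.81 and 4.96 in cKO replicates 1, 2 and 3, so cKO replicate 1 lay below all 3 wild-type libraries. The p53 and apoptosis genes were lower for 13 of 20 members with a median of -0.25 (adjusted p = 0.0142, but adjusted p = 0.668 with an estimated correlation). They included Eda2r at 7.30 ± 3.86 and 3.13 ± 1.00 FPKM and Ccng1 at 87.6 ± 41.3 and 45.3 ± 12.3 FPKM, both targets of p53. The list mean was 3.89, 3.87 and 3.70 in the wild-type libraries and 3.60, 3.76 and 3.48 in the cKO libraries. The estimated correlation of the p53 list was -0.01, below the preset 0.01. Its p before adjustment over the lists was 0.0353 with that estimate, against 0.00415 with the preset (camera). A higher correlation was thus not the reason for this rise, and the losses of other lists need not rest on correlation alone. Cholesterol synthesis genes were lower for 14 of 21 members with a median of -0.07 (adjusted p = 0.0433, but adjusted p = 0.668 with an estimated correlation), led by Fdft1, the squalene synthase gene, at 16.9 ± 3.42 and 11.3 ± 2.06 FPKM. The mean of cholesterol genes was 3.66, 3.53 and 3.33 in the wild-type libraries and 3.37, 3.47 and 3.36 in the cKO libraries, so wild-type replicate 3 was the lowest of all 6. In these 4 lists, 0 members passed over all genes or adjusted over the list alone. At the preset correlation, the inflammatory call ended without cKO replicate 2 (adjusted p = 0.108), and the p53 call with the stricter filter (0.114) and without cKO replicate 3 (0.124). The interferon call ended with that filter (0.136), with a pseudocount of 0.1 (0.0631) and without wild-type replicate 2 (0.0563), wild-type replicate 3 (0.381), cKO replicate 2 (0.382) or cKO replicate 3 (0.772), and the cholesterol call with that filter (0.136) and without wild-type replicate 1 (0.510), wild-type replicate 2 (0.0697), cKO replicate 1 (0.166) or cKO replicate 3 (0.152).

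The remaining 13 lists did not pass. Immediate early and heat shock genes had a median log2 difference of 0.37 (camera, preset correlation, adjusted p = 0.0980), with the AP-1 gene Fosl1 at 6.98 ± 2.95 and 21.5 ± 6.81 FPKM and Junb at 81.3 ± 21.1 FPKM in wild-type and 165.1 ± 48.5 FPKM in cKO libraries. Peritubular myoid markers had a median of -0.31 (adjusted p = 0.0531), with Tagln at 13.8 ± 6.94 and 5.27 ± 0.905 FPKM. Hypoxia response genes had a median of 0.34 (adjusted p = 0.260), mitochondrially encoded transcripts -0.18 (0.120), retinoic acid genes 0.06 (0.793) and spermatogonia and spermatocyte markers 0.38 (0.754). For 6 lists the median, mean and direction of the test differed in sign. The medians were 0.06 for glycolysis and lactate supply (adjusted p = 0.754), 0.03 for the cell cycle (0.782), 0.02 for phagocytosis (0.458) and 0.01 for collagens and matrix (0.793), and the test pointed down for these 4. Sertoli secreted factors had a median of -0.18 and a mean of 0.08 (adjusted p = 0.663), and rete testis and epididymal markers -0.06 and 0.11 (0.782), and the test pointed down for both. Some of these lists passed at the preset correlation in other settings. Without wild-type replicate 3 these were the cell cycle (adjusted p = 0.000110, lower), hypoxia (0.000758, higher), myoid (0.000758, lower) and spermatogonia and spermatocyte lists (0.0146, higher), each lost with an estimated correlation (adjusted p = 0.543 for myoid and 0.708 for the others). Without cKO replicate 3 they were hypoxia (0.000762, higher), immediate early (0.0110, higher), mitochondrially encoded (0.000762, lower) and myoid lists (0.00242, lower), also lost with an estimated correlation (adjusted p = 0.663 for hypoxia and 0.569 for the others). Immediate early genes also passed without wild-type replicate 1 (0.0314) and with quantile normalization (0.0147), and glycolysis genes without cKO replicate 1 (0.0423, lower), and with an estimated correlation these had adjusted p = 0.882, 0.644 and 0.719. Erythroid markers had fewer than 3 tested members and were not tested.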

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

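The GC and length corrections, the look at GC trends and the left-out libraries of the ribosomal protein tests were chosen after seeing the data, and the other settings before. Arhgef15 kept its direction and stayed short of the threshold in every setting run, with log2 differences from 0.06 (pseudocount 5) to 1.05 (pseudocount 0.1), where the pseudocount sets the scale of so low a gene. Its adjusted p was lowest with array weights, at 0.0684, and next lowest without wild-type replicate 3, at 0.252 (limma). The filter settings do not apply to its fit. The 2 genes called, both lower and both at least 2-fold, stayed 2 with the stricter filter, median-ratio scaling, quantile normalization, both pseudocounts, array weights, an adjusted p threshold of 0.1 and the GC and length correction. Counts of genes differing, lower and at least 2-fold were 0 without the filter, 0 with the replicate block and 0 with GC and length correction and the block, and 1 each with predicted genes left out, which removes Rps12-ps3 by construction. The cause of the other losses was not tested, and Rps27rt kept a log2 change of -3.26 without the filter (adjusted p = 0.0938; over its settings 0.00391 to 0.413). Leaving out 1 library gave 0 to 478 genes differing, 0 to 304 higher, 0 to 174 lower and 0 to 459 at least 2-fold; the highest values all came without wild-type replicate 3, and both main genes were among the 478. Gene lists past the threshold numbered 11, and 4 with the stricter filter (Sertoli, junction, inflammatory and macrophage), which left fewer members, 0 with the correlation estimated, 0 with the fry directional test, and 7 to 12 with 1 library left out (7 without wild-type replicate 2). The replicate numbers did not meet the criterion for pairing: same-number correlations of deviations were 0.138, 0.032 and -0.206, and not every library correlated best with its own number. Same-numbered libraries did share the sign and rough size of a trend over GC content (Spearman across genes, wild-type and cKO: 0.41 and 0.48, -0.17 and -0.13, -0.40 and -0.29), so a shared preparation was not excluded. The block left 11 lists. Among the leading named genes, 8 calls were gained, all without wild-type replicate 3, 8 were lost with 1 library left out and 6 in other settings, all of Rps27rt or Rps12-ps3, and 0 reversed. In the simulation, with noise independent between genes, changes of 2-fold were mostly out of reach at the spread of all 6 libraries. The estimated correlation, run after seeing the data within the other settings too, left 0 lists in each.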

Other observations

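The tests of the 3 patterns below, the count of splits for pseudogenes included, were chosen only after the results were seen, and for ribosomal proteins the demand that an exclusion hold with each library left out was added later still, after those values were seen. The other counts over splits follow a fixed procedure, but what they would show was also written down only then. Wild-type replicate 3 and cKO replicate 1 shared high germ cell transcripts. The mean log2(FPKM + 1) of 10 spermatogonia and spermatocyte markers was 4.35 and 4.36 in these libraries and 1.31 to 2.08 in wild-type replicates 1 and 2 and cKO replicates 2 and 3. Ldhc, the lactate dehydrogenase of germ cells, was at 70.2 and 99.3 FPKM in these libraries and at 2.49 to 5.06 FPKM in the others, and Dazl, a germ cell RNA-binding protein, at 27.4 and 17.2 FPKM against 0.391 to 2.92 FPKM. Within wild-type, replicate 3 was above both other replicates for 19 of 19 hypoxia genes and below both for 25 of 30 cell cycle genes.

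Without wild-type replicate 3, 478 genes passed, and the examples that follow were chosen after their values were seen. Vegfd, a lymphatic growth factor, had a log2 change of -3.45 (limma, adjusted p = 0.0106), and Lyz2 -3.42 (0.00767). Serpinb2 had 4.10 (0.0160), the claudin gene Cldn4 4.07 (0.0155), Pdgfb 3.54 (0.00391) and the matrix gene Tnc 3.02 (0.00391). With all 6 libraries these adjusted p were 0.701, 0.652, 0.770, 0.786, 0.608 and 0.611. Wild-type replicate 3 reached the range of the cKO libraries or passed it in 332 of the 478 genes, and that of the other wild-type libraries in 19.

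Over the 10 splits of the 6 libraries, 3 against 3, no share under 0.1 can be had, too few for chance to be tested at 0.05. As many genes differing as the real 2 were found in 2 splits, and the highest other split, wild-type replicates 1 and 2 with cKO replicate 3, gave 19, which points to a structure of the samples. Other splits have no fixed direction, so the larger of their directions was counted for higher and for lower genes alike. For genes higher, real count 0, all 10 splits gave as many, with 17 the highest other. For genes lower, real count 2, it was 2 splits, with 17 the highest other, and for genes at least 2-fold, real count 2, it was 2 splits, with 19 the highest other. For gene lists, real count 11, it was 6 splits, with 14 the highest other.

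The first pattern is that wild-type replicate 3 lay nearer the cKO libraries than wild-type replicates 1 and 2. Only a lower share of Sertoli cells in wild-type replicates 1 and 2 would move the markers of every other cell type alike, but endothelial and macrophage markers moved apart by 2.35 (log2, bootstrap 95% interval over genes 1.81 to 3.49). The interval treats genes as independent, though the estimated correlation of the endothelial list was 0.67. The test also assumes that endothelial markers came from endothelial cells. In wild-type replicate 3 they rose by a median of 1.24 (log2), against 1.19 for junction genes and 0.84 for Sertoli markers. A Sertoli cell source of these transcripts was not excluded. Spermatogonia and spermatocyte markers, however, lay above both other wild-type libraries in wild-type replicate 3 for 10 of 10 genes, with a median shift of 2.94 (log2). Macrophage markers shifted by a median of -1.11. A difference in Sertoli share alone would move both lists down, so these values argue against it for wild-type replicate 3. A different Sertoli share as part of the pattern stays open. Cultures with different shares of macrophages are a candidate explanation for part of the first pattern. Of 15 macrophage markers, all from a list fixed beforehand, 13 were lower in wild-type replicate 3 than in both other wild-type libraries. Lyz2 was at 66.5 against 647.8 and 576.9 FPKM. A wrong genotype label cannot be told apart from a different culture. Wild-type replicate 3 was nearer the cKO mean in 70.6% of tested genes, while at Rps27rt and Rps12-ps3 it lay with wild-type at 424.6 and 927.4 FPKM. These 2 genes were called with this library counted as wild-type, so its place there was partly set by that choice. Both also passed without this library, but as 2 of 478 genes. Its place at these genes may follow litter or strain, which was not tested, so it does not decide for or against a wrong label. Processed pseudogenes and ribosomal protein genes also separated most under the labelled grouping. Their shares not overlapping were 24.4% and 35.8%, against at most 12.4% and 22.2% in other groupings. Other coding genes did not, with 10.3% against up to 19.9%. The genotype itself stays open and untested.

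The second pattern is that ribosomal protein transcripts were lower in the libraries labelled cKO, with 62 of 81 genes lower and a median log2 change of -0.34 (-0.15 with quantile normalization, -0.22 with 56 of 81 lower after GC and length correction, -0.18 without wild-type replicate 1). By library, the median deviation from the mean of all libraries was 0.57, 0.13 and -0.11 in wild-type and -0.07, -0.09 and -0.31 in cKO replicates 1, 2 and 3. Wild-type replicate 3 thus lay slightly below 2 of the 3 cKO libraries, and the median log2 change of the cKO mean against it alone was -0.09. All cKO values lay below all wild-type values in 27 of the 81 genes and above them in 2. Together this was 35.8% of them, the highest of the 10 splits (highest other 22.2%), too few splits to test chance. Fragments exchanged between a gene and its named copies would leave family sums level, and GC content or transcript length alone would lower matched coding genes as much. The sums of all 42 families differed by -0.37 (median, bootstrap 95% interval over families -0.55 to -0.27) and the genes differed from matched ones by -0.30 (-0.38 to -0.15), but without wild-type replicate 1 these were -0.24 (-0.33 to -0.06) and -0.16 (-0.30 to -0.04), so the bound of -0.1 set for excluding either was not met and both stay open, while strain, read handling and genotype stay untested. Processed pseudogenes went both ways, with all cKO values below all wild-type values in 98 of 660 and above them in 63, together 24.4% where chance gives 10% (reached by 1 of the 10 splits, the real one, highest other 12.4%), and with a median of -0.06 that became 0.06 after GC and length correction.

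The third pattern is that Arhgef15 was not lower in the libraries labelled cKO. Fragments from endothelial cells in the cultures are a candidate source, since Arhgef15 is known from vascular endothelium. Over 6 libraries Arhgef15 followed the mean of 12 endothelial markers, 1 of 24 lists compared, with Spearman's rho 1.00 (exact permutation p = 0.0028, adjusted p = 0.067) and Pearson's r 0.98 (exact permutation p = 0.0014, adjusted p = 0.034), and r was 0.96 without wild-type replicates 1 and 2. Other lists came close, with r 0.91 and rho 0.94 for retinoic acid genes, r 0.74 and rho 0.94 for spermatogonia and spermatocyte markers, r 0.89 and rho 0.77 for Sertoli markers and r -0.91 and rho -0.66 for fibroblast markers (exact permutation, adjusted p from 0.116 to 0.323). Without the 2 farthest libraries of each, r was 0.77, 0.78, 0.08 and -0.21 for these lists. On the same measure r was -0.97 for mitochondrially encoded transcripts, -0.95 for p53 genes, 0.95 for glycolysis genes and 0.92 for rete testis markers. For lists not given here it was -0.64 to 0.85. The relation was therefore not shown to be specific to endothelial cells. With 6 libraries, and with the abundant endothelial marker Cdh5 at 27.0 to 55.6 FPKM but Pecam1 at 0.263 to 7.99 FPKM, this source cannot be told apart from Sertoli cell transcript outside the deleted exons or from incomplete deletion.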
